A study of Mus musculus with 2 samples.

How the data were processed

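RNA-seq was carried out on 2 libraries of organoids grown from mouse pituitary, 1 of cystic and 1 of dense organoids. Organoids are cell clusters that grow in culture from tissue and keep part of its organisation. Per the labels' protocols, both were kept in PitOM medium, RNA was taken with a micro-scale column kit, amplified with Smart-seq v4 and made into libraries with an NEBNext DNA kit. Smart-seq copies full-length transcripts from small amounts of RNA by PCR, without molecular identifiers in the counts used here, so reads are not independent molecules.

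The authors deposited 1 table with a value per gene and library, a normalized read signal in units of normalized counts. Per the submitters' processing notes, TopHat, DESeq 1.32.0 and the mm9 mouse build were used. Which step each served, the read counter, the TopHat version and the annotation are not given in the sources used here. Each column holds whole multiples of its smallest value above 0, for 100% of values within a tolerance of 0.001 read. The deposited signal is therefore a whole read count divided by 1 size factor per library, 0.956 for cystic and 1.05 for dense organoids, and the reads were recovered from it. No row of the deposited table is at 0 in both libraries. It has 20649 rows, of which 2 are ERCC spike-in rows, with 0 reads in the cystic and 2 reads in the dense library. These 2 rows were left out, leaving 20647 genes. Of the Ensembl identifiers, 20589 (99.7%) are also in GENCODE release M21, an annotation of the GRCm38 build. The table gives no coordinates and its named build differs from that of the annotation at hand, so no coordinates are printed.

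The recovered depth was 17247431 reads in the cystic and 19258313 reads in the dense library. One read equals 1.05 normalized counts in the cystic and 0.956 in the dense library. A count of 0 was taken to allow up to 3 reads, a floor of 3.14 normalized counts in the cystic and 2.87 in the dense library. Intervals on values are exact Poisson intervals and intervals on folds are exact Clopper-Pearson intervals, both at 95%. For a gene at 0 in a library the fold is a lower bound against 3 reads in that library. The exact Poisson interval for 0 reads reaches further, to 3.86 normalized counts in the cystic and 3.53 in the dense library. Such a fold also leaves out the counting error of the other library, so it is not the lower end of a 95% interval. The intervals and floors cover counting error only, not the spread between cultures or mice.

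With 1 library per group there was no test between conditions, and no p-value was computed. The following choices were made before the data were examined. Ratios were taken as log2 of cystic over dense after a pseudocount of 1 was added to each value, and genes needed a mean of the 2 values of at least 50. A gene was called higher in a library at a 4-fold difference, a log2 ratio of 2. In all, 28 gene lists were fixed, and 25 of them had at least 3 measured members. For each, the median log2 ratio was set against 10000 random lists of the same size, drawn from 20 bins of mean expression. A list is said to stand apart when its median lies below percentile 2.5 or above percentile 97.5, which describes these libraries only. By chance 1.25 of 25 lists would do so. Genes of one list vary together in any pair of cultures, which random lists do not imitate. A list can stand apart although its members differ in both directions, so a percentile does not mean that all members shifted alike.

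Named genes are the 15 with the highest and the 15 with the lowest ratio among genes with a mean of at least 500, unnamed gene models and small RNA genes left out. From each list, up to 4 measured members with the largest ratio either way and the 2 with the highest mean could be named. Hormone genes, Sox2, Sox9, Pitx1, Lhx3, Pou1f1 and the sex check genes are given at any level. Some genes that this rule covers are not reported here. Values near those of close paralogs are uncertain where reads could be shared, as in the Krt6, Krt14 and Krt16, Sprr2, Cyp2a, Saa and Ly6 families, and in ribosomal protein genes with processed pseudogenes.

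The ratio rule was tested on simulated counts for this comparison, with 11290 genes past the filter. It called 100% of 43 genes changed 6-fold, 1 of 36 changed 3-fold (2.78%), 0 of 45 changed 2-fold and 0 of 11090 unchanged genes. The simulated counts held Poisson counting noise only, with no spread between cultures or mice and no amplification noise. These calls therefore check the rule against counting noise and give no rate of false calls between separate cultures. Of 200 random lists of simulated genes, 6% stood apart. Alternatives were other pseudocounts, filters and thresholds, 3 other scalings (total, upper quartile and trimmed mean of M-values from edgeR 4.0.16 in R 4.3.3), the mean in place of the median, and lists without their most abundant member. Alternatives added after the data were seen were a count of genes by their counting interval on the recovered reads, lists without genes shared with other lists or with the named genes, and lists with genes at 0 set to the floor. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.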

Results

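Gene expression was compared between cystic and dense organoids derived from the pituitary of male mice aged 10 weeks. The cystic library came from passage 2 of a culture from a GHCre/iDTR mouse, and the dense library from passage 4 of a culture from a -/iDTR mouse. Organoid type, passage and mouse therefore differ together between the 2 libraries. Depth was 17247431 reads for cystic and 19258313 for dense organoids. Reads were found in 18362 genes in the cystic and 17814 in the dense library. The 10 most abundant genes took 9.58% of the cystic and 6.84% of the dense normalized counts, and mitochondrially encoded genes took 0.659% and 0.450%. There were no replicates, so each difference below is a description of 2 libraries, with intervals for counting error only.

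The libraries of cystic and dense organoids differed widely. Most measured secretory, inflammatory, interferon response and pituitary lineage genes were higher in the cystic library. Among the measured lineage factors, 1, Pitx1, was higher in the dense library. Most measured stratified epithelial genes were higher in the dense library. Among 11279 genes past the expression filter, 886 were at least 4-fold higher in cystic organoids and 863 at least 4-fold higher in dense organoids, together 15.5%. A 100-fold difference was passed by 234 genes in favour of cystic and 221 in favour of dense organoids. No read was found in the dense library for 223 genes with at least 50 normalized counts in the cystic library, and 184 genes showed the opposite. Across these 11279 genes, which are not independent replicates, the log2 values correlated with Pearson's r = 0.51 and Spearman's rho = 0.73. When a gene had to have its whole 95% counting interval beyond 4-fold, 785 genes were higher in cystic and 780 in dense organoids. That count, chosen after the data were seen, compares these libraries and not the conditions.

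**Figure D1:**
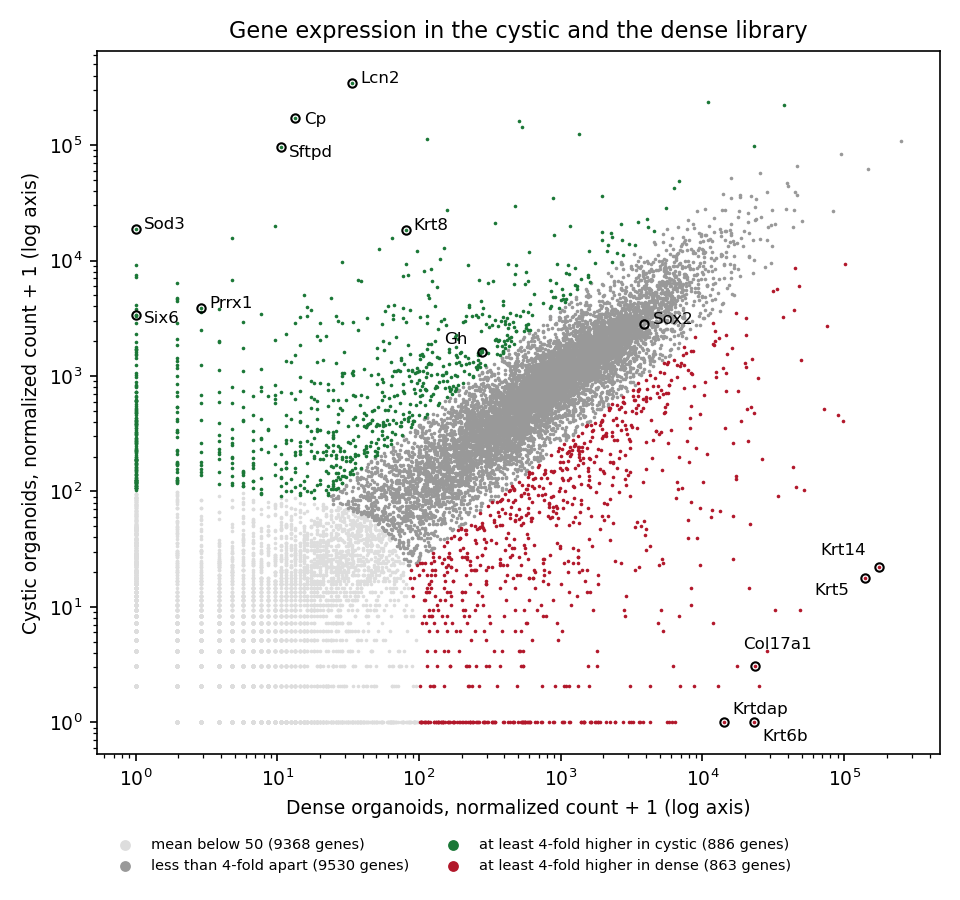
Each point is a gene, with its normalized count plus 1 in the dense library on the x axis and in the cystic library on the y axis, both log axes, 1 library per group. Green points are the 886 genes at least 4-fold higher in cystic organoids and red points the 863 at least 4-fold higher in dense organoids, grey points are the other genes; Lcn2 and Cp lie at the upper left and Krt14 and Krt5 at the lower right.

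The genes highest in cystic relative to dense organoids included genes of secreted and membrane proteins. Lcn2 (ENSMUSG00000026822), an iron-scavenging defence protein, was the most abundant of them, with 347061 normalized counts in cystic and 32.5 in dense organoids, a 10679-fold difference (95% counting interval 7642 to 15420). Cp (ENSMUSG00000003617), the copper-carrying ferroxidase ceruloplasmin, had 173377 against 12.4, which is 13952-fold (8159 to 26204). Sftpd (ENSMUSG00000021795), the collectin surfactant protein D, had 96428 against 9.56, or 10088-fold (5485 to 21038). Sod3 (ENSMUSG00000072941), the extracellular superoxide dismutase, had 18815 normalized counts in cystic organoids and no read in dense organoids, so it was at least 6561-fold higher. Also without a read in the dense library were Kng2 (kininogen), A2ml1, Chil1, the fatty acid transporter Slc27a2, the lipid receptor Cd36, the basement membrane gene Nid2, the eye and pituitary homeobox gene Six6, the endotoxin-binding gene Lbp and Iqgap2. Their lower bounds ran from 993-fold for Iqgap2 to 3195-fold for Kng2. Prom1, which encodes the membrane protein CD133, had 15660 against 3.82 (4096-fold, 1599 to 15034). Rorb, a nuclear receptor gene, had 6339 against 0.956, the latter a single read (6631-fold, 1190 to 261968).

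The genes highest in dense relative to cystic organoids included keratin genes and other genes of stratified epithelium. Krt14 (ENSMUSG00000045545) and Krt5 (ENSMUSG00000061527), the keratin pair of basal epithelial cells, had 175149 and 139723 normalized counts in dense organoids against 20.9 and 16.7 in cystic organoids. These are 8371-fold (5420 to 13705) and 8347-fold (5140 to 14604) differences. Krt6b (ENSMUSG00000023041) had 23260 and no read in cystic organoids, at least 7411-fold higher, although its reads may be split with Krt6a. Krt16 had 49131 against 8.37 (5870-fold, 2979 to 13598). Col17a1, the hemidesmosomal collagen, had 23534 against 2.09 (11248-fold, 3113 to 92880), and Lama3, a laminin chain of epithelial basement membrane, had 8712 against 1.05 (8327-fold, 1494 to 328949). Cdsn (corneodesmosin) had 17582 against 2.09 (8403-fold, 2326 to 69393) and Dmkn (dermokine) had 28685 against 3.14 (9140-fold, 3127 to 44321). Adh7, an alcohol and retinol dehydrogenase gene, had 12946 against 1.05 (12375-fold, 2221 to 488822). Krtdap, Ndufa4l2, Endou, Nccrp1, Sprr2d and Sprr2h had no read in cystic organoids, with lower bounds from 1360-fold for Sprr2h to 4494-fold for Krtdap. The Sprr2 genes are near-identical copies and their separate values are uncertain.

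Pituitary stem cell genes included several that were much higher in cystic organoids. The list of 21 genes had 17 measured members, of which 7 were at least 4-fold higher in cystic organoids and 1 at least 4-fold higher in dense organoids. Its median log2 ratio was 0.90 (percentile 99.9 of matched random lists). Of the measured members, 12 were higher in cystic and 5 in dense organoids at any size of difference. The member at least 4-fold higher in dense organoids was Klf4, chosen after its values were seen. Klf4 had 2819 normalized counts in dense and 205 in cystic organoids (13.7-fold, 11.9 to 15.97). Prrx1, a homeobox gene, had 3856 against 1.91 normalized counts (2017-fold, 558 to 16662), and Aldh1a2, a retinoic acid synthesis gene, had 3545 against 1.91 (1855-fold, 513 to 15320). Krt8 and Krt18, the keratins of simple epithelium, were 232-fold (187 to 291) and 39.2-fold (36.7 to 41.9) higher in cystic organoids. Ly6a was 4.30-fold higher in cystic organoids (4.23 to 4.36), with 99055 against 23062, although its reads may be shared with close paralogs. Cd9 was 1.49-fold higher in dense organoids (1.46 to 1.52). Sox2, the stem cell transcription factor of the gland, was present in both, with 2790 in cystic and 3885 in dense organoids (1.39-fold higher in dense, 1.33 to 1.46), and Sox9 had 2842 and 1527 (1.86-fold higher in cystic, 1.75 to 1.98).

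Of 17 pituitary lineage transcription factors, 7 were measured, 5 at least 4-fold higher in cystic organoids and 1, Pitx1, at least 4-fold higher in dense organoids. The median log2 ratio was 2.24 (percentile 99.9). Six6 was at least 1181-fold and Lhx3, a factor of early pituitary commitment, at least 59.8-fold higher in cystic organoids, since the dense library held no read of either. Isl1 was 15.8-fold (12.3 to 20.6) higher in cystic organoids. Pitx1, an oral ectoderm and pituitary homeobox gene, had 1276 in cystic and 5614 in dense organoids (4.40-fold higher in dense, 4.13 to 4.68). Pou1f1, the factor of the somatotroph, lactotroph and thyrotroph lineages, had 2.09 normalized counts in cystic and 34.4 in dense organoids.

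Hormone transcripts were present in both libraries and higher in the cystic one. Gh (growth hormone) had 1603 against 276 normalized counts (5.80-fold, 5.11 to 6.60), Prl (prolactin) 1192 against 251 (4.74-fold, 4.14 to 5.44) and Pomc, the precursor of ACTH, 1021 against 146 (6.98-fold, 5.88 to 8.33). Cga, the shared glycoprotein hormone subunit, had 113 against 13.4 (8.44-fold, 4.82 to 15.96). Tshb, Lhb and Fshb stayed below the filter, with 22.0, 11.5 and 15.7 in cystic and 4.78, 1.91 and 8.60 in dense organoids. The granule genes Chgb and Chga were 10.99-fold (7.15 to 17.7) and 6.57-fold (3.84 to 11.9) higher in cystic organoids. The list had 18 genes and 8 measured members, 7 of them at least 4-fold higher in cystic organoids, with a median log2 ratio of 2.59 (percentile 99.9). The exception was Cpe, a prohormone-processing enzyme gene, with 14666 in cystic and 16415 in dense organoids.

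**Figure D2:**
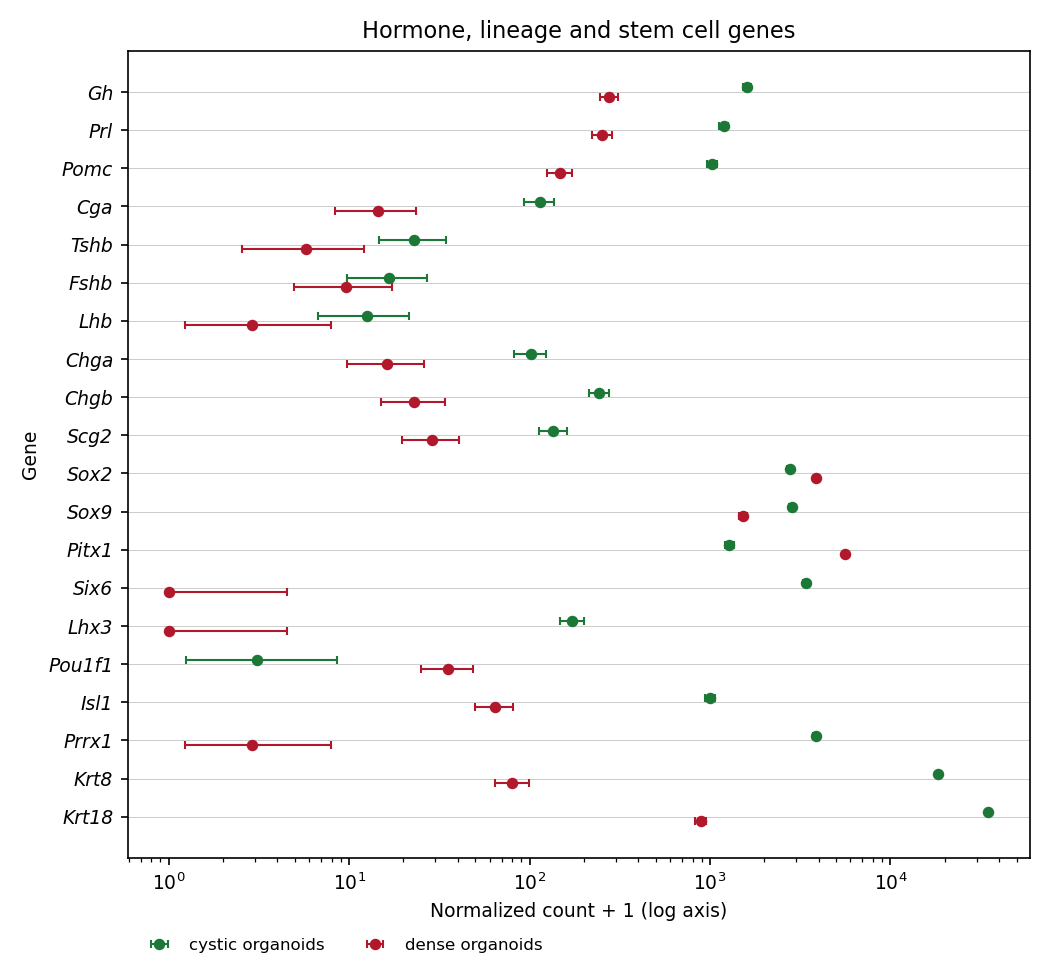
Normalized count plus 1 on a log x axis for selected hormone, lineage and stem cell genes on the y axis, with green points for the cystic and red points for the dense library; bars are exact 95% Poisson intervals for counting error, 1 library per group. Gh, Prl and Pomc lie to the right in the cystic library, Sox2 is close in both, and Six6 and Lhx3 have no read in the dense library.

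Basal and squamous epithelial genes were far higher in dense organoids. Of 20 measured members of the list of 21, 18 were at least 4-fold higher in dense organoids and 0 in cystic organoids, with a median log2 ratio of -7.34 (percentile 0), which was -5.96 with a pseudocount of 50. Besides Krt14, Krt5 and Krtdap, Sprr1b, a cornified envelope precursor gene, had 2395 against no read and was at least 763-fold higher. Secretory and glandular genes showed the reverse. Of 24 genes, 8 were measured, 7 of them at least 4-fold higher in cystic organoids, with a median log2 ratio of 8.22 (percentile 100). This median was 8.03 with genes at 0 put at the floor of 3 reads, 7.06 without genes shared with other lists or among the 30 named genes, 5.52 with 17 members of a mean of at least 1 and 5.37 with a pseudocount of 50. Ltf (lactoferrin) had 236771 against 10991 (21.5-fold, 21.1 to 22.0), Pigr, the immunoglobulin transporter gene, had 5046 against 14.3 (352-fold, 213 to 629), and Reg3g, an antibacterial lectin gene, was at least 252-fold higher. Ciliated cell genes were mostly below the filter, with 2 of 18 measured. Foxj1, the regulator of motile cilia, had 126 against no read (at least 43.8-fold), and Cfap43 was 4.13-fold higher in dense organoids (3.59 to 4.76).

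Junction, adhesion and transport genes differed in both directions. Of 23 tight junction and desmosome genes, all measured, 8 were at least 4-fold higher in cystic and 7 in dense organoids. Among the claudin genes, Cldn9 in the cystic library was at 1856 against 0.956 (1942-fold, 348 to 76731), Cldn6 at 1247 against 0.956 (1305-fold, 234 to 51572) and Cldn3 174-fold higher (128 to 244). Cldn1, chosen after its values were seen, was 69.5-fold higher in dense organoids (52.0 to 95.1). The desmosome genes Pkp1, Dsc2 and Jup were 510-fold (418 to 628), 28.0-fold (26.9 to 29.1) and 7.96-fold (7.75 to 8.18) higher in dense organoids. The median log2 ratio was 0.54 (percentile 99.6), and it turned to -0.033 with members of a mean of at least 200. Of 18 measured basement membrane and integrin genes, 8 were at least 4-fold higher in dense and 2 in cystic organoids (median -1.37, percentile 0.01; -0.64 with members of a mean of at least 200). Col4a2 was 149-fold higher in dense organoids (57.8 to 547), Itgb8 at least 213-fold higher in cystic organoids, and Itga3, with 13956 against 7163, was 1.95-fold higher in cystic organoids (1.89 to 2.00).

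Of 16 measured fluid and ion transport genes, 8 were at least 4-fold higher in dense and 3 in cystic organoids, and at any size of difference 8 were higher in each library. In cystic organoids the sodium pump subunit gene Atp1b1 had 20039 against 8.60 (2329-fold, 1227 to 5095) and the water channel gene Aqp5 had 112934 against 113 (1001-fold, 836 to 1210). In dense organoids Car12, a membrane carbonic anhydrase gene, had 21647 against 51.3 (422-fold, 319 to 571) and Fxyd3 was 91.4-fold higher (52.1 to 177). The list median of -1.23 (percentile 0.09) lay in the gap between members that differed in opposite directions and turned to 0.53 with members of a mean of at least 1 and to 0.31 with members of a mean of at least 200.

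Inflammatory and interferon response genes were higher in cystic organoids. Of 16 measured cytokine and acute phase genes, 9 were at least 4-fold higher in cystic organoids and 1, Il1a, in dense organoids (median log2 ratio 2.57, percentile 100). Saa3 was at least 684-fold, Hp at least 118-fold and Cxcl17 at least 61.3-fold higher, and the complement gene C3 had 27265 against 156 (175-fold, 150 to 205). Il33 had 17208 against 2277 (7.56-fold, 7.24 to 7.89). Il1a had 491 in dense organoids and a single read in cystic organoids. Of 15 measured interferon response genes, 11 were at least 4-fold higher in cystic and 0 in dense organoids (median 3.83, percentile 100; 2.39 with a pseudocount of 50). Oasl2 had 1421 against 0.956 (1486-fold, 266 to 58748), Ifi44 was 686-fold (234 to 3331), Isg15 43.5-fold (24.1 to 87.7) and Bst2 15.6-fold (13.1 to 18.7) higher, and Mx1 was at least 36.8-fold higher. Of 11 immune cell markers, 1 passed the filter, the lysosomal gene Cd68, with 373 in cystic and 3123 in dense organoids. Among those below it, chosen after their values were seen, the leukocyte gene Ptprc had 1.05 in cystic organoids and no read in dense organoids, and Aif1 had 47.1 and no read.

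**Figure D3:**
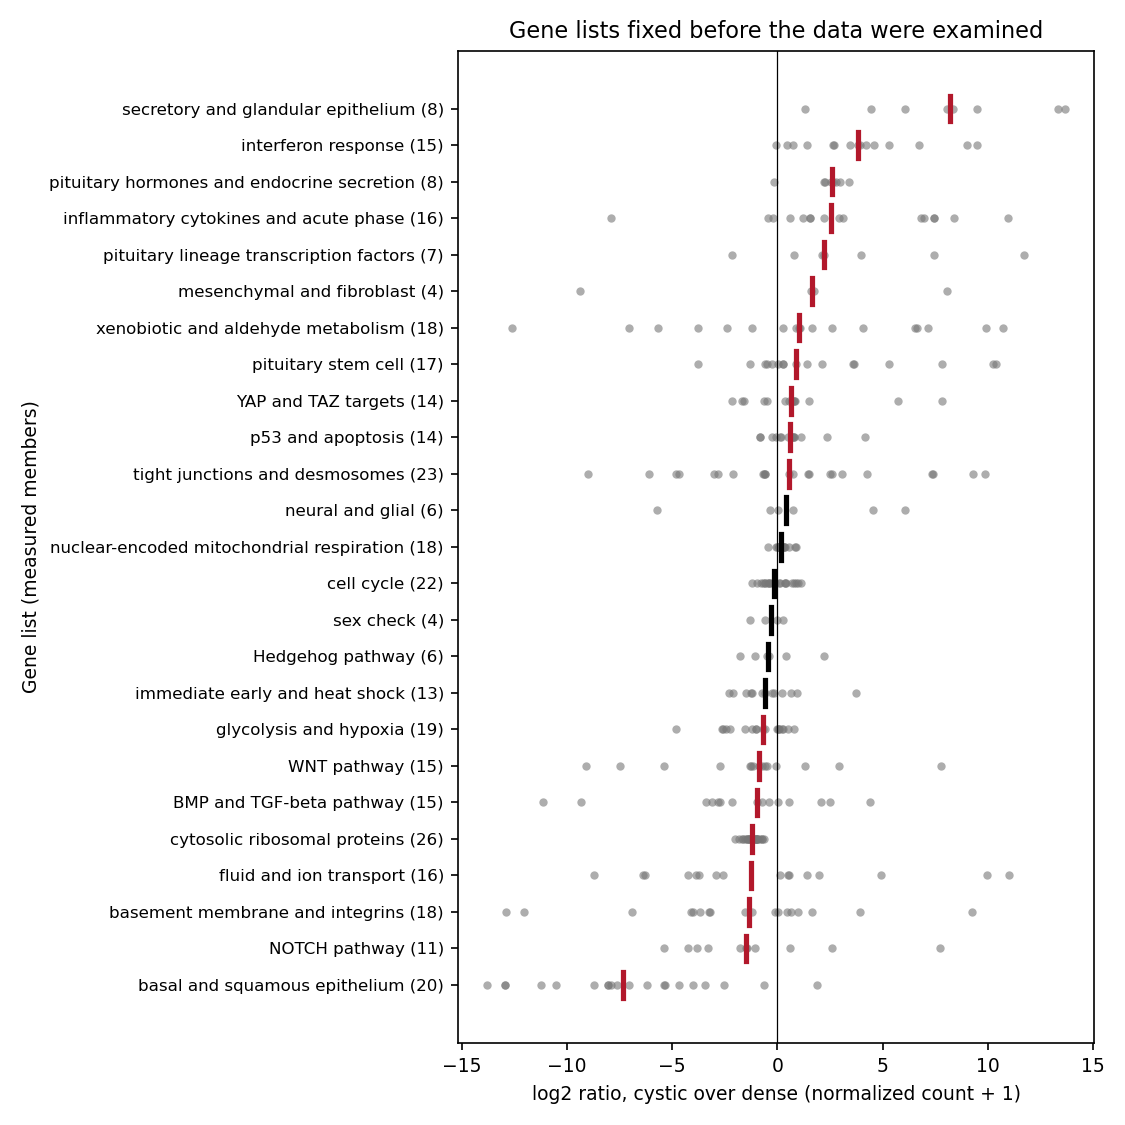
Each row on the y axis is a gene list with its number of measured members in parentheses, grey points are members by log2 ratio of cystic over dense on the x axis, and bars mark the median, red where it stood apart from matched random lists and black where it did not. The secretory list has the highest median at 8.22 and the basal and squamous list the lowest at -7.34.

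Signalling pathway genes differed member by member. In the NOTCH list, 4 of 11 measured genes were at least 4-fold higher in dense and 2 in cystic organoids (median -1.51, percentile 0.05). The ligand gene Jag2 was 41.3-fold (37.1 to 46.2), the receptor gene Notch1 18.9-fold (16.01 to 22.5) and the target Nrarp 14.0-fold (11.8 to 16.8) higher in dense organoids. The target Hey1 was 233-fold higher in cystic organoids (136 to 438). In the WNT list, 4 of 15 measured genes were at least 4-fold higher in dense and 2 in cystic organoids (median -0.85, percentile 0.22). Wnt10a was 609-fold (309 to 1411) and Wnt11 43.3-fold (30.03 to 64.9) higher in dense organoids and Wnt7a at least 56.3-fold higher. The stem cell receptor gene Lgr5 had 423 in cystic organoids and a single read in dense organoids, and Wnt7b was 7.64-fold higher in cystic organoids (7.29 to 8.002). In the BMP and TGF-beta list, 7 of 15 genes were at least 4-fold higher in dense and 3 in cystic organoids (median -0.97, percentile 0.05). The median was -2.44 with 10 members of a mean of at least 200 and -1.56 without the most abundant member. Bmp2 had 1312 in dense organoids and a single read in cystic organoids, Bmp7 was 10.7-fold higher in dense organoids (9.44 to 12.1) and Tgfbi at least 712-fold higher, whereas Tgfb3 was 21.3-fold higher in cystic organoids (18.0 to 25.3) and Id2 had 1749 and 1738. Of the 14 YAP and TAZ targets, Ctgf was 241-fold (144 to 442) and Ankrd1 80.4-fold (21.9 to 670) higher in cystic organoids and Axl 4.46-fold (3.85 to 5.18) higher in dense organoids (median 0.63, percentile 99.3). At any size of difference, 9 of these targets were higher in cystic and 5 in dense organoids. The 6 measured Hedgehog genes did not stand apart (median -0.46, percentile 14.5); Cdon was 4.71-fold higher in cystic organoids (3.45 to 6.54) and Gas1 3.40-fold higher in dense organoids (3.13 to 3.69).

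Cell cycle genes did not stand apart. None of the 22 members, all measured, differed 4-fold, and the median log2 ratio was -0.16 (percentile 23.0), with the widest ratios at Ccne1, 2.32-fold higher in dense organoids (2.03 to 2.65), and Rrm2, 2.17-fold higher in cystic organoids (2.01 to 2.35). All 26 cytosolic ribosomal protein genes were lower in cystic organoids, with a median of -1.22 (percentile 0) and a range from -2.03 to -0.65. Rplp0 had 7995 against 16008 and Rpl4 8753 against 27618, although reads of such genes may be shared with processed pseudogenes. In contrast, 18 nuclear-encoded mitochondrial respiration genes had a median of 0.17 (percentile 87.2), with Atp5b at 23002 and 23682. Of 19 glycolysis and hypoxia genes, 5 were at least 4-fold higher in dense organoids (median -0.71, percentile 0.49). These included Ndrg1 at 28.6-fold (25.3 to 32.5), the glucose transporter gene Slc2a1 at 6.15-fold (5.87 to 6.44) and Vegfa at 6.07-fold (5.58 to 6.61), whereas the abundant enzyme genes Pkm and Ldha were 1.42-fold and 1.18-fold higher in cystic organoids.

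Xenobiotic and aldehyde metabolism genes included some of the most abundant transcripts. Of 18 measured, 7 were at least 4-fold higher in cystic and 5 in dense organoids (median 1.04, percentile 99.99), so the list divided in both directions. Its widest log2 ratio, -12.6, was that of Adh7, higher in dense organoids. In cystic organoids Cyp2f2, a cytochrome P450 gene, had 124911 against 1338 (93.3-fold, 88.5 to 98.5), Cyp2a5 had 3785 against 2.87 (1320-fold, 451 to 6403) and Fmo1 was at least 598-fold higher. Aldh1a3, chosen after its values were seen, had 17143 in dense organoids and 128 in cystic organoids (134-fold, 112 to 162). Gsto1 was the most abundant gene of the dense library, with 253377 there and 109591 in cystic organoids. Of 14 genes of the p53 and apoptosis list, Gdf15 and Ccng1 were 18.3-fold (12.6 to 27.7) and 5.10-fold (4.96 to 5.25) higher in cystic organoids (median 0.60, percentile 98.5). At any size of difference, 10 genes of this list were higher in cystic and 4 in dense organoids. The 13 measured immediate early and heat shock genes did not stand apart (median -0.60, percentile 3.48), with Nr4a1 13.6-fold higher in cystic organoids (11.95 to 15.4) and Hspb1 4.85-fold higher in dense organoids (4.59 to 5.13).

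Few endothelial and mesenchymal markers passed the expression filter, which 11279 of all 20647 genes passed. None of the 10 endothelial genes passed the filter. Of 19 mesenchymal genes 4 did, with a median of 1.66 (percentile 98.1). Snai2 was 770-fold higher in dense organoids (353 to 2099), Cdh2 at least 91.6-fold higher in cystic organoids, Fn1 3.35-fold (3.07 to 3.66) and S100a4 3.003-fold (2.42 to 3.74) higher in cystic organoids. Of 13 neural and glial genes, 6 were measured (median 0.40, percentile 76.7), with Ncam1 24.2-fold higher in cystic organoids (16.4 to 37.0) and Tubb3 at 2.09 in cystic and 164 in dense organoids. Both mice were labelled male. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 1162, 1166, 372 and 1096 normalized counts in cystic and 1773, 1194, 930 and 912 in dense organoids. Xist was not analysed here.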

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

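The alternatives with recovered reads, genes at 0 set to the floor and lists without shared genes were chosen after seeing the data. Of the 19 lists that stood apart, 17 kept the sign of their median under every alternative run. Percentiles were not recomputed under the alternatives, so whether the lists would still stand apart was not tested. Among 275 alternative list values, 26 differed from the main median by more than 1.5-fold. The fluid and ion transport median of -1.23 turned to 0.53 with members of a mean of at least 1 and to 0.31 with a mean of at least 200. The tight junction and desmosome median of 0.54 turned to -0.033 with a mean of at least 200. Fewer or more members entered each of these medians. Without its most abundant member the transport median was -2.57. With a pseudocount of 50 the medians were -0.63 for transport, -5.96 for squamous, 5.37 for secretory, 1.69 for hormone, 1.81 for inflammatory and 2.39 for interferon genes, and 6.95 for secretory genes with a pseudocount of 10. With members of a mean of at least 1 they were 5.52 for secretory genes and 1.63 for lineage factors, and with a mean of at least 200 they were -2.44 for BMP and TGF-beta and -0.64 for basement membrane genes. Without the most abundant member they were -1.56 for BMP and TGF-beta genes and 3.05 for lineage factors, and without shared or named genes -6.19 for squamous, 7.06 for secretory and -0.64 for basement membrane genes. Means in place of medians were 2.33 for stem cell genes, 3.73 for lineage factors, 0.50 for mesenchymal, -1.82 for BMP and TGF-beta, -0.51 for transport, -2.003 for basement membrane and 3.29 for inflammatory genes. Of 150 alternative ratios of the 30 named genes, 57 lay outside the counting interval of the main ratio, all of them with a pseudocount of 10 or 50, which lowers large ratios by construction. The count of genes higher in cystic organoids, 886, became 2681 with no filter on the mean, 561 with a mean of at least 200 and 1767 at 2-fold. That of dense organoids, 863, became 1939 with no filter and 1761 at 2-fold. These follow from how many genes enter or from the threshold. The 3 other scalings moved the median ratio of all genes by 0.02 to 0.09, and cystic calls made up 50.7% of all calls as deposited and 52.8% at most among them. Pearson's r across genes was 0.67 with a mean of at least 10 and 0.36 with a mean of at least 200, and Spearman's rho was 0.79 and 0.64. Genes without a read in the dense library numbered 421 with at least 20 and 90 with at least 200 normalized counts in the other library, and those without a read in the cystic library 287 and 93. Depth limits statements on genes under about 3 reads. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out.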

Other observations

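The genes and families in the next paragraphs, and the tests on hormone and squamous transcripts and of ribosomal protein genes against all other measured genes, were chosen after the values were seen; the tests on length, GC content and other scalings of ribosomal protein genes were set before their results were seen. Besides Krt8 and Krt18, the simple epithelial keratins Krt7 and Krt19 were 116-fold and 187-fold higher in cystic organoids. Among transcription factors, Tbx1 had 1992 normalized counts in cystic and 2.87 in dense organoids, Msx1 6208 and 556, Foxa1 1098 and 33.5, and Sox11 221 and no read. Foxe1, a factor of thyroid and palate development, had 55.4 in cystic and 2015 in dense organoids, and Grhl3, a regulator of epidermal barrier genes, 120 and 3779. Sox15 had no read in cystic organoids and 1141 normalized counts in dense organoids, Pax9 no read and 342, and Tfap2c 1.05 and 1085. The epithelial factors Ehf and Elf3 were abundant in both, with 7283 and 6760 in cystic and 6547 and 4430 in dense organoids. Msln (mesothelin) had 161161 in cystic and 506 in dense organoids.

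Genes of the epidermal differentiation complex, taken as the neighbours from S100a1 to S100a10 in the RefSeq annotation of GRCm38, were mostly higher in dense organoids. Of 39 measured genes, 29 were at least 4-fold higher there, 11 of them Sprr genes whose separate values are uncertain for the Sprr2 copies. Several of the 29, such as Sprr3 and Sprr1b, are also members of the squamous list. The highest count in 10033 other windows of 39 neighbouring measured genes was 12. These windows overlap, so they are not separate comparisons. Of the other measured genes of the complex, 3 were at least 4-fold higher in cystic organoids, S100a8, S100a9 and S100a1, at 16.8-fold, 7.85-fold and 11.2-fold. All 8 measured kallikrein-related peptidase genes and 7 of 9 Tmprss protease genes were at least 4-fold higher in dense organoids. Klk8 had 8358 against 9.42 and Tmprss11b 9542 against 22.0. Of 9 Serpinb protease inhibitor genes, 5 were at least 4-fold higher in dense organoids, among them Serpinb5 with 6834 against 7.32, and 1, Serpinb7, was 17.9-fold higher in cystic organoids. All 3 measured guanylate-binding protein genes were at least 4-fold higher in cystic organoids, with Gbp9 at 275 against 5.74.

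Hormone transcripts in cultures of passage 2 and 4 were several-fold higher in the cystic library. Leakage of reads between the 2 libraries was argued against, because the dense value of Gh was 17.2% of the cystic value (15.1 to 19.6), while Cp, Lcn2 and Sod3 allow a leak of at most 0.0123%. A second candidate explanation is a single source of endocrine cells or their RNA, present in both in different amounts, which needs like folds for genes that only this source expresses. Without Cpe, left out because both libraries held it far above any hormone (14666 and 16415), the median fold of 7 hormone and granule genes was 6.57, and 6 of them were within 1.5 times that median, but Chgb was at 10.99 (7.15 to 17.7). None of these 7 had its interval wholly outside 2 times the median, a limit set after the values were seen. Within it, the intervals of Prl (4.14 to 5.44) and Pomc (5.88 to 8.33) did not overlap, while that of Gh (5.11 to 6.60) overlapped both. The folds of Prl and Pomc thus differed by more than counting error, which leaves out amplification and spread between cultures. A single source is therefore neither shown nor excluded, and Pou1f1 was higher in dense organoids (34.4 against 2.09). Organoid type, passage and mouse were not tested and stay open.

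Several squamous genes were detected at a low level in cystic organoids. Krt17 had 458 normalized counts there, Krt6a 406, Dsg3 161 and Sprr1a 536, which are 0.507%, 0.415%, 0.369% and 2.42% of their levels in dense organoids. Over the 19 squamous genes that were higher in dense organoids, this share ran from 0 for Krtdap and Sprr1b to 64.4% for Krt10. Perp, with 9241 normalized counts in cystic organoids, was at 9.15%. Reads leaking from the dense library were argued against, since Krt6b, the strictest of Krt14, Krt5 and Krt6b, allows at most 0.0135%. Of the 19 squamous genes, 15 had lower bounds above this. Reads of Krt6b may be split with Krt6a, but the lowest lower bound of these 15, 0.0341% for Dsc3, also exceeded the upper bounds of Krt5 and Krt14. The median was 1.04% over the 12 of the 19 squamous genes that are not keratins and 0.415% over the 7 keratin genes. This does not settle whether misassigned keratin reads contribute at Krt17, Krt6a and the other keratin genes. A few whole cells of the dense type, with its levels of Krt5 and Krt14, were argued against by these genes. Their upper bounds of 0.0195% and 0.0185% lie below the median of 0.507% over the 19 squamous genes that were higher in dense organoids. Krt5 and Krt14 are among the genes with the lowest ratios, so this order was known when the test was chosen. A low level of part of this programme within cystic cells, or squamous cells without Krt5 and Krt14, may remain as a hypothesis, and neither was tested.

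All 26 cytosolic ribosomal protein genes were lower in the cystic library, with a median log2 ratio of -1.22. Biases by transcript length and GC content were tested on the longest annotated transcript of each gene, which need not be the one expressed. The list lay at percentile 0.03 among lists matched on that length and mean and at percentile 0 among lists matched on GC content and mean. This argues against a bias by annotated length or GC content. A bias by the length or GC content of the expressed transcripts was not tested. Under 3 other scalings the median was -1.13 at the highest, but these moved all genes alike by at most 0.09 and decided nothing by themselves. However, 1 factor per library cannot set a list apart, and the list median differed by -1.19 from that of all other measured genes (-0.031). An interval for the list median, taken over its 26 members, ran from -1.42 (the ratio of Rpl8) to -1.002 (that of Rplp0). It treats the members as independent, although genes of one list vary together, so it describes their spread in these libraries only. The list median was known when this comparison was chosen, so the comparison is a description and not a separate test. Organoid type, passage and mouse, and reads shared with processed pseudogenes, were not tested and stay open, so a biological difference is a hypothesis only.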
